A study of Saccharomyces cerevisiae S288C and Saccharomyces cerevisiae W303 with 12 samples.

How the data were processed

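Transcript levels of budding yeast were measured on 12 two-colour oligonucleotide arrays, each hybridized with cRNA from 1 culture and with cRNA from a common reference, a wild-type BY4742 pool. Per the labels, the strains carry tor1-1, lack FPR1, express the ribosomal protein Rpl13A fused to FKBP12 and carry Abf1, Rap1 or Reb1 fused to FRB, so that rapamycin tethers the tagged factor to an exported ribosomal protein and removes it from the nucleus (anchor-away depletion). The 12 arrays form 6 groups of 2, given by strain (abf1-aa, rap1-303-aa, reb1-aa) and by time (0 or 30 min). Each group holds 2 independent cultures, called a and b in the labels. The letter coincides with the dye, since the sample was in Cy3 on the a arrays and in Cy5 on the b arrays. The labels of reb1-aa also carry isolate numbers that differ between a and b.

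The scanner files hold, per the file headers, the signal and local background intensity of each spot in both channels, with no background removed and no normalization, from image analysis software not given in the sources used here. A table of log2 ratios normalized by the authors was also deposited, as sample over reference for each spot and array, by a method not given in the sources used here. It was used as an alternative. Depth is given for arrays as signal over local background. Median signals over the gene spots lay between 251 and 806 per channel and array, against median backgrounds of 18 to 69, and between 97.2% and 99.7% of the named genes exceeded the background by 2.6 of its standard deviations. The number of arrays, 2 per group, limits the precision.

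Each array carries 15552 spots in 48 blocks. Of these, 12776 are gene spots (6388 probes, 2 spots each), 1872 are external control spots (14 probes) and 904 are quality control spots. A table supplied with the data paired 5326 probes with a gene name. The other 1062 probes had no single name and were left out of the gene tests. A RefSeq gene table of assembly R64 was used for current names (54 updated, 6 names not found in it) and for the order of neighbouring genes, with strands taken from the systematic names. For 11 genes with 2 probes the brighter probe was used, which left 5315 named genes. The gene annotated as FPR1 has no named probe, so the planned check of the FPR1 deletion was replaced, after the data were seen, by the levels of URA3, LYS2, LEU2, TRP1, HIS3, ADE2 and MET17.

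Signals were corrected for background with normexp (offset 50) and normalized within arrays by loess over the gene spots in limma 3.58.1 under R 4.3.3. Every log2 ratio was turned to sample over reference and the 2 spots of a probe were averaged. Per gene, lmFit and eBayes fitted the 6 groups and a dye term to all 12 arrays (5 residual degrees of freedom, prior 4.01). The fit estimated the change from 0 to 30 min in each strain and the difference of these changes between each pair of strains. Values are log2 changes ± standard error (SE) of limma, with 2 cultures at each time, and Benjamini-Hochberg adjustment ran over the 5315 genes. A gene counted as changed at an adjusted p under 0.05. This spread is pooled over the 3 strains.

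For groups of genes, 18 lists were fixed before the data were examined: cytosolic ribosomal proteins, ribosomal protein genes known as Abf1-associated, glycolysis and fermentation, translation factors, ribosome biogenesis, RNA polymerase I and III subunits, general stress response, heat shock factor chaperones, nitrogen catabolite genes, amino acid biosynthesis, a-specific mating genes, alpha-specific mating genes, haploid-specific and pheromone pathway genes, subtelomeric families, oxidative phosphorylation, mitochondrial ribosomal proteins, proteasome subunits and core histones. The name pattern for ribosomal proteins also took in RPP1, a subunit of RNase P and RNase MRP. Each list was tested with limma's camera against all other genes (preset correlation 0.01), adjusted over the 54 tests within strains and, separately, over the 54 tests between strains. Members past the threshold were counted after adjustment over all genes and adjusted over the list alone.

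Named genes followed a rule also fixed before the data were examined: per strain, the 10 largest rises and 10 largest falls among changed genes whose change had the same sign in the a and b arrays, up to 2 changed members per list with the largest change, and always ABF1, RAP1 and REB1. Between strains the rule took the 3 largest differences in each direction, and for changes shared by the 3 strains the 5 genes per direction whose smallest change was largest. Genes outside this rule are named as such.

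The steps were tested on simulated data with 50 changed genes per fold size in each strain among the 5315 genes. At 1.5-fold, 47 of 50 were recovered in abf1-aa, 43 in rap1-303-aa and 49 in reb1-aa. At 1.25-fold the numbers were 15, 16 and 20, and at 2-fold all 50 were recovered in each strain. Among unchanged genes, 7 of 5085, 11 of 5115 and 13 of 5115 passed. The simulated noise was independent between probes and had the same pooled spread in all strains, so these numbers do not compare the strains in sensitivity.

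Alternatives, each changing 1 choice, were no background subtraction, plain subtraction, median centring, print-tip loess, Aquantile scaling between arrays, normalization on 4 external control probes, leaving out the dimmest 25% of probes, no dye term, culture pair as replicate block, only the arrays compared, eBayes with trend and robust settings, the deposited ratios, an adjusted p under 0.01, a further 1.7-fold minimum, each array left out in turn, and, for lists, camera with an estimated correlation and fry. Median centring and normalization on external controls took the place of loess, with 1 shift per array, so they also left out its correction for intensity. An error in that shift moves all genes of an array together and widens their spread. Added after the data were seen were the spot median, array weights per strain, all gene probes tested and a crossed pairing of cultures. Aquantile scaling leaves log ratios as they are by construction. Neighbouring genes were compared with Fisher's exact test and with 100000 shuffles of the genes that fell.

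Lists defined by DNA motifs or by distance from telomeres were not analysed here, because no genome sequence was at hand. An alternative on unflagged spots was not run, since the scanner files carry no spot flags. With 2 arrays per group, no test by regrouping the samples was possible at the level of 1 comparison. No strain without a tagged factor is among the samples, so the effect of rapamycin alone was not measured.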

Results

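The arrays compared transcript levels before and 30 min after rapamycin in 3 anchor-away strains of budding yeast, which lose Abf1, Rap1 or Reb1 from the nucleus. All 3 are general regulatory factors that bind promoter DNA, and the series deals with promoter sequence, the +1 nucleosome and binding of the TATA-binding protein. Each strain and time had 2 cultures on 2 arrays with swapped dyes, always against the same wild-type reference. Signals of gene spots had medians of 419 to 806 on the abf1-aa arrays, 251 to 562 on the rap1-303-aa arrays and 365 to 764 on the reb1-aa arrays. Changes of the a and b arrays correlated across the 5315 genes, which are not independent replicates, with r of 0.76 in abf1-aa, 0.52 in rap1-303-aa and 0.98 in reb1-aa. All genes that changed did so with the same sign in both. By the labels, strain backgrounds derive from S288C or W303. Ratios to the reference also depend on which marker genes the reference lacks, which was not examined. The strain rap1-303-aa differed from the others at 0 min in marker genes. Its log2 ratio to the reference was 3.65 ± 0.07 (SD, n = 2) for URA3, 2.71 ± 0.45 for LYS2, 1.46 ± 0.48 for LEU2 and 1.32 ± 0.06 for TRP1, whereas these means lay between -0.29 and 0.08 in the 2 other strains. HIS3 (-1.04 ± 0.05) and ADE2 (-0.87 ± 0.04) were low in it, against -0.40 and -0.15 in abf1-aa and -0.19 and -0.18 in reb1-aa. MET17 was lowest in reb1-aa (-1.13 ± 0.11), with -0.60 ± 0.04 in rap1-303-aa and -0.13 ± 0.04 in abf1-aa.

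Transcripts of the tagged factors themselves were compared with the reference and over time. At 0 min ABF1 stood at -0.78 ± 0.19 (log2 ratio to the reference, SD, n = 2) in abf1-aa, REB1 at -0.84 ± 0.11 in reb1-aa and RAP1 at 0.78 ± 0.07 in rap1-303-aa. By 30 min ABF1 rose by 0.42 ± 0.09 in abf1-aa (limma adjusted p = 0.0110), while RAP1 in rap1-303-aa (0.33 ± 0.12, adjusted p = 0.197) and REB1 in reb1-aa (0.19 ± 0.09, adjusted p = 0.211) did not pass the test. RAP1 fell in reb1-aa (-0.53 ± 0.12, adjusted p = 0.0161). The call of ABF1 ended without the abf1-aa 0 min a array (0.36, adjusted p = 0.0805) or the 30 min a array (0.35, adjusted p = 0.0801). That of RAP1 in reb1-aa ended without the 0 min b (-0.42, adjusted p = 0.166), 30 min a (-0.47, adjusted p = 0.144) or 30 min b array (-0.59, adjusted p = 0.0557), and after normalization on external controls (-0.38, adjusted p = 0.979). ABF1 also did not pass without the dye term (adjusted p = 0.0563), with only the abf1-aa arrays (adjusted p = 0.0620) or after normalization on external controls (0.78, adjusted p = 0.549). These tests use a spread pooled over the strains without pairing, although the a and b changes of reb1-aa differed less across genes (SD 0.07) than those of abf1-aa (0.28) and rap1-303-aa (0.27). With only the reb1-aa arrays REB1 passed (adjusted p = 0.000511), as it did with array weights (adjusted p = 0.000902) and from the deposited ratios (0.22, adjusted p = 0.0419), but not with culture pair as replicate block (adjusted p = 0.183). RAP1 in reb1-aa passed with only those arrays (adjusted p = 7.00e-07) and with the block (adjusted p = 0.0312). In rap1-303-aa, RAP1 passed with print-tip loess (0.31, adjusted p = 0.0192) and from the deposited ratios (0.37, adjusted p = 0.00283). There it was 0.15 without the 30 min a array and 0.51 without the 30 min b array.

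After 30 min of rapamycin in abf1-aa, 745 of 5315 genes fell and 345 rose. Falls were larger, with 199 falls and 13 rises beyond 1 log2 unit. After normalization on external controls 30 genes fell and 21 rose, and from the deposited ratios 933 fell and 598 rose. FCF1, which encodes a pre-rRNA processing factor, fell by 2.52 ± 0.07 on the log2 scale (limma adjusted p = 1.78e-07, n = 2 cultures per time). TPM2, a tropomyosin gene, fell by 2.42 ± 0.07. Close behind were the prefoldin gene GIM3 (-2.33 ± 0.11), TFB1 of the general transcription factor TFIIH (-2.27 ± 0.07), the RNA helicase gene DHR2 (-2.23 ± 0.10) and CET1 of the mRNA capping enzyme (-2.19 ± 0.13). NHX1, an endosomal sodium/proton exchanger gene, fell by 2.18 ± 0.10, and TMA46, which encodes a ribosome-associated protein, by 2.08 ± 0.12. Among the rises were CIT2, the peroxisomal citrate synthase gene (1.56 ± 0.09, adjusted p = 3.54e-06), TMA10 (1.39 ± 0.13), RGI1 (1.33 ± 0.16), FMP45 (1.26 ± 0.12), PHM8 (1.18 ± 0.10) and BDH2 (1.04 ± 0.10). So were the little-studied YER053C-A (1.23 ± 0.08) and YLR297W (1.05 ± 0.09).

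Genes for building ribosomes fell as a group in abf1-aa. Of 79 ribosome biogenesis genes, 62 fell and none rose (68 fell when adjusted over the list alone), with a mean of -0.68. At an unadjusted p under 0.05 there were 69 falls and 0 rises in limma. The list passed camera (adjusted p = 6.81e-25; adjusted p = 0.175 with an estimated correlation). Its examples were the helicase gene DBP9 (-2.09 ± 0.09) and UTP11 of the small-subunit processome (-2.00 ± 0.08). Subunits of RNA polymerases I and III also fell, 10 of 19 (13 adjusted over the list alone) with a mean of -0.44 (camera adjusted p = 2.02e-05; adjusted p = 0.155 with an estimated correlation). They included RPO31, the largest subunit of polymerase III (-1.64 ± 0.09), and RPC40, shared by both enzymes (-1.06 ± 0.13).

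General stress genes rose in abf1-aa, 33 of 36 (35 adjusted over the list alone) with a mean of 0.68 (camera adjusted p = 1.05e-17; adjusted p = 0.249 with an estimated correlation). HXK1, a hexokinase gene, rose by 1.19 ± 0.17 and PGM2, a phosphoglucomutase gene, by 1.08 ± 0.19. Nitrogen catabolite genes, which serve as a readout of rapamycin action on TOR signalling, had 8 rises and 1 fall among 27 members (the same numbers adjusted over the list alone), with a mean of 0.16 (camera adjusted p = 0.00737; adjusted p = 0.155 with an estimated correlation). The amino acid permease gene DIP5 rose by 0.61 ± 0.06, and GZF3, a GATA-type repressor gene, fell by 0.77 ± 0.09. Heat shock factor chaperones moved apart, with 4 rises and 4 falls among 17 members (12 and 4 adjusted over the list alone), a mean of 0.14 and a median of 0.38. HSP42, a small heat shock protein gene, rose by 0.97 ± 0.19 and STI1, an Hsp90 co-chaperone gene, fell by 1.43 ± 0.09. That list passed camera (adjusted p = 0.0373; adjusted p = 0.547 with an estimated correlation). It did not pass without the 0 min b array (mean 0.03, adjusted p = 0.146) or the 30 min a array (mean 0.12, adjusted p = 0.112), and HSP42 did not pass without the 0 min b array (0.64, adjusted p = 0.0559). The list was also lost with print-tip loess (adjusted p = 0.0565), normalization on external controls (mean 0.55, adjusted p = 0.0561), no dye term (adjusted p = 0.0532), the deposited ratios (adjusted p = 0.0630) and by fry (adjusted p = 0.273).

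Other lists did not pass camera in abf1-aa, though some of their members changed strongly. By fry, proteasome subunits (adjusted p = 0.00571), mitochondrial ribosomal proteins (adjusted p = 0.0120), translation factors and Abf1-associated genes (adjusted p = 0.0226 each) passed. So did amino acid biosynthesis (adjusted p = 0.0446) and subtelomeric families (adjusted p = 0.0498). Mitochondrial ribosomal protein genes had 17 falls and 2 rises among 70 (17 and 3 adjusted over the list alone; mean -0.18, adjusted p = 0.886). MRPL32 stood at -2.12 ± 0.09 and RSM27 at -2.06 ± 0.08. Proteasome subunits had 9 falls and 2 rises among 32 (9 and 4 adjusted over the list alone; mean -0.17, adjusted p = 0.515). SCL1 stood at -1.33 ± 0.14 and RPN13, a ubiquitin receptor gene, at -1.01 ± 0.09. Translation factors had 7 falls and 2 rises among 25, both also adjusted over the list alone (mean -0.25, adjusted p = 0.0695). The termination factor gene SUP35 was at -1.77 ± 0.14 and TIF35 of the initiation machinery at -1.19 ± 0.09. Oxidative phosphorylation genes had 7 falls and 6 rises among 36 (8 and 15 adjusted over the list alone; mean -0.03, adjusted p = 0.143). The ATP synthase genes ATP18 (-1.58 ± 0.16) and ATP14 (-1.45 ± 0.14) fell. Amino acid biosynthesis had 4 falls and 1 rise among 35, both also adjusted over the list alone (mean -0.11, adjusted p = 0.976). They included ARO3 of aromatic amino acid synthesis at -2.01 ± 0.07 and TRP3 at -1.40 ± 0.10. Of the cytosolic ribosomal protein list, 4 of 126 genes fell (1 adjusted over the list alone; mean -0.06, adjusted p = 0.413). They included RPP1 of RNase P and RNase MRP (-0.37 ± 0.09), which did not pass without the 0 min b (-0.34), 30 min a (-0.36) or 30 min b array (-0.38), with median centring (adjusted p = 0.0753), without the dye term (adjusted p = 0.138) or with only the abf1-aa arrays (adjusted p = 0.0744). They also included RPP1A (-0.70 ± 0.08), which encodes a ribosomal stalk protein and also belongs to the 6 genes known as Abf1-associated (1 fall over all genes and adjusted over the list alone; mean -0.22, adjusted p = 0.207). COS5 was the only subtelomeric gene of 28 to change, by 0.44 ± 0.08 (also 1 adjusted over the list alone; mean 0.08, adjusted p = 0.0762).

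In abf1-aa the means were 0.11 for glycolysis and fermentation (adjusted p = 0.208), -0.01 for a-specific (adjusted p = 0.976), 0.12 for alpha-specific (adjusted p = 0.515) and 0.10 for haploid-specific genes (adjusted p = 0.140), and 0.04 for core histones (adjusted p = 0.606). No member of these 5 lists passed limma's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1 in glycolysis and 2 among haploid-specific genes, with 0 in the 3 others. Signs differed between median, mean and test for amino acid biosynthesis (median 0.02, test down), oxidative phosphorylation (median 0.17, test up), mitochondrial ribosomal proteins (median 0.07, test down), proteasome (median 0.04, test down) and a-specific genes (median -0.03, test up). The number of changed genes was 620 without the 0 min b array and 723 without the 30 min b array, and 51 after normalization on external controls.

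In rap1-303-aa, 218 of 5315 genes fell and 89 rose by 30 min, 44 and 8 of them beyond 1 log2 unit. CMS1, linked to small-subunit ribosome assembly, fell by 2.81 ± 0.07 on the log2 scale (limma adjusted p = 6.00e-08, n = 2 cultures per time). PRO1 of proline synthesis (-2.67 ± 0.12), the alcohol dehydrogenase gene SFA1 (-2.61 ± 0.10), the nucleolar protein gene RRP14 (-2.31 ± 0.07), NEW1, which encodes an ABC-type translation protein (-2.19 ± 0.07), and PHO81, a regulator gene of phosphate signalling (-2.12 ± 0.11), fell as well. The largest rises were of the uncharacterized YOR292C (1.44 ± 0.13), STE2 (see the mating genes), ALT2, an alanine transaminase homologue (1.34 ± 0.09), YGR035C (1.16 ± 0.08), the peroxiredoxin gene AHP1 (1.12 ± 0.10), the drug efflux pump gene PDR5 (1.10 ± 0.13) and GRE2, a reductase gene (1.08 ± 0.12). STF1, a regulator of the ATP synthase (1.00 ± 0.15), ROX3 of Mediator (0.97 ± 0.09) and the dihydrofolate reductase gene DFR1 (0.94 ± 0.12) followed. Without the 0 min a array STF1 did not pass (0.83, adjusted p = 0.0589).

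Cytosolic ribosomal protein genes fell as a group in rap1-303-aa, with 37 falls and 1 rise among 126 (65 and 2 adjusted over the list alone) and a mean of -0.37 (camera adjusted p = 1.27e-24; adjusted p = 0.107 with an estimated correlation). RPS7B fell by 1.97 ± 0.11 and RPS27A by 1.52 ± 0.08. Of the 6 genes known as Abf1-associated, RPL4A fell by 0.47 ± 0.08 (1 fall, with 1 rise and 1 fall adjusted over the list alone; list mean -0.05, adjusted p = 0.914). It did not pass without the 0 min a array (-0.39, adjusted p = 0.124), with median centring (-0.39, adjusted p = 0.176), the spot median (-0.34, adjusted p = 0.151), array weights (adjusted p = 0.0868) or only the rap1-303-aa arrays (adjusted p = 0.0593). Of 79 ribosome biogenesis genes, 3 fell over all genes and adjusted over the list alone, among them TSR1, needed for small-subunit maturation (-2.19 ± 0.13), and FAF1 (-0.95 ± 0.12). The mean of that list was -0.11 (camera adjusted p = 0.0160; adjusted p = 0.736 with an estimated correlation). It was -0.03 with median centring (adjusted p = 0.566) and 0.05 with normalization on external controls (adjusted p = 0.546), and it did not pass by fry (adjusted p = 0.321). It was also -0.08 without the 0 min a array (adjusted p = 0.151) and -0.01 without the 30 min b array (adjusted p = 0.889). RPA43, an RNA polymerase I subunit gene, was the only 1 of 19 in its list to fall (-0.82 ± 0.12, also the only 1 adjusted over the list alone; mean -0.07, adjusted p = 0.317). It did not pass without the 0 min a array (-0.79, adjusted p = 0.0518).

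Mating-type genes changed in rap1-303-aa. MATALPHA2 (-2.35 ± 0.11) and MATALPHA1 (-2.13 ± 0.09), the regulators of alpha cell identity, fell, and so did SST2, a negative regulator of pheromone signalling (-2.27 ± 0.13), and STE3, the a-factor receptor gene (-1.64 ± 0.12). Probes for MATALPHA1 and MATALPHA2 also match the silent copies at HML. Of 7 a-specific genes, 3 rose (4 adjusted over the list alone) with a mean of 0.42 (camera adjusted p = 9.74e-06; adjusted p = 0.216 with an estimated correlation). The largest rises were of STE2, the alpha-factor receptor gene (1.38 ± 0.09), and the a-factor gene MFA2 (0.69 ± 0.06; adjusted p = 0.0770 with median centring). STE3 was the 1 of 4 alpha-specific genes that fell, and none of that list rose (1 up and 1 down adjusted over the list alone; median 0.15, mean -0.17, adjusted p = 0.896). Haploid-specific genes had 2 rises and 1 fall among 16, over all genes and adjusted over the list alone (median 0.01, mean -0.05, test up, adjusted p = 0.510). The rises included that of the agglutinin gene AGA1 (0.59 ± 0.14), which did not pass without the 0 min a (0.58, adjusted p = 0.264), 0 min b (0.60, adjusted p = 0.234) or 30 min b array (0.34, adjusted p = 0.119), nor with culture pair as replicate block (adjusted p = 0.0571), plain background subtraction (adjusted p = 0.0552), no dye term (adjusted p = 0.282) or array weights (adjusted p = 0.219).

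Mitochondrial ribosomal protein genes rose in rap1-303-aa, with 8 rises and 2 falls among 70 (21 and 2 adjusted over the list alone) and a mean of 0.21 (camera adjusted p = 5.21e-16; adjusted p = 0.107 with an estimated correlation). MRPL49, however, fell by 1.41 ± 0.09. So did MRP7, by 0.88 ± 0.21, but not without the 0 min a (-0.98), 0 min b (-0.78) or 30 min b array (-0.52), nor with culture pair as replicate block (adjusted p = 0.0521), median centring (adjusted p = 0.0879), no dye term (adjusted p = 0.160), the spot median (adjusted p = 0.0515) or array weights (adjusted p = 0.266). Proteasome genes had 2 rises and 1 fall among 32 (9 and 1 adjusted over the list alone) and a mean of 0.17 (camera adjusted p = 1.59e-07; adjusted p = 0.155 with an estimated correlation). PRE2, a catalytic subunit gene, fell by 1.09 ± 0.10. The core subunit gene PRE10 rose by 0.36 ± 0.08, but not without the 0 min a (0.33), 0 min b (0.39) or 30 min a array (0.25), nor with culture pair as replicate block (adjusted p = 0.0561), median centring (adjusted p = 0.104), no dye term (adjusted p = 0.0917), the spot median (adjusted p = 0.0528), array weights (adjusted p = 0.242) or only the rap1-303-aa arrays (adjusted p = 0.172). Glycolysis and fermentation genes had a mean of 0.29 (camera adjusted p = 0.00243; adjusted p = 0.155 with an estimated correlation). In this list 0 of 16 members passed limma's test, over all genes or adjusted over the list alone, and 4 rose at an unadjusted p under 0.05. This call was lost with median centring (mean 0.04, adjusted p = 0.948), print-tip loess (mean 0.19, adjusted p = 0.0680), normalization on external controls (mean 0.13, adjusted p = 0.766), the deposited ratios (mean 0.23, adjusted p = 0.145) and without the 30 min b array (mean 0.23, adjusted p = 0.125).

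Small mean changes of 4 further lists passed camera in rap1-303-aa and were lost when 1 array was left out. Translation factors had a mean of 0.10 (adjusted p = 0.0373; adjusted p = 0.605 with an estimated correlation; 0.02 without the 30 min a array, adjusted p = 0.660). It had 1 rise among 25 (2 adjusted over the list alone), that of EFB1, an elongation factor gene (0.45 ± 0.07). EFB1 did not pass with median centring (0.22, adjusted p = 0.251), the deposited ratios (0.32, adjusted p = 0.103), only the rap1-303-aa arrays (adjusted p = 0.0593) or array weights (adjusted p = 0.106). Subtelomeric families had a mean of 0.09 (adjusted p = 0.0192; adjusted p = 0.347 with an estimated correlation; 0.09 without the 30 min b array, adjusted p = 0.194). Oxidative phosphorylation had a mean of 0.07 (adjusted p = 0.0373; adjusted p = 0.658 with an estimated correlation; 0.04 without the 30 min a array, adjusted p = 0.274). Core histones had a mean of 0.19 (adjusted p = 0.0496; adjusted p = 0.658 with an estimated correlation; 0.08 without the 30 min a array, adjusted p = 0.540). Leaving out the 0 min b array also ended these 4 calls (means 0.08, 0.07, 0.04 and 0.18, adjusted p = 0.135, 0.149, 0.267 and 0.0827). That of the histones ended without the 0 min a array too (mean 0.20, adjusted p = 0.0826), and with culture pair as replicate block (adjusted p = 0.0509). With only the rap1-303-aa arrays the 4 adjusted p values were 0.0754, 0.0915, 0.114 and 0.0526. All but the subtelomeric list were also lost with print-tip loess (adjusted p of at least 0.121), the deposited ratios (adjusted p = 0.132, 0.253 and 0.204) and fry (adjusted p = 0.273, 0.321 and 0.364). Median centring ended the calls of translation factors (adjusted p = 0.362) and histones (adjusted p = 0.547), and external controls those of translation factors, histones (adjusted p = 0.487 each) and subtelomeric families (adjusted p = 0.0923). In the last 3 lists no member passed limma's test, over all genes or adjusted over the list alone, and 6, 2 and 1 rose at an unadjusted p under 0.05.

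General stress genes did not pass camera in rap1-303-aa (mean 0.00, adjusted p = 0.538). Of 36 members, 1 rose and 2 fell (1 and 3 adjusted over the list alone). The falls were those of GPD1 of glycerol synthesis (-1.33 ± 0.12) and HSP78, a mitochondrial chaperone gene (-1.03 ± 0.12). HSP78 was also the only 1 of 17 heat shock factor chaperones to change, over all genes and adjusted over the list alone (mean 0.00, adjusted p = 0.538). Nitrogen catabolite genes had 1 rise and 2 falls among 27, over all genes and adjusted over the list alone (mean 0.01, adjusted p = 0.748). The falls were those of UGA3, a regulator gene of GABA use (-0.39 ± 0.08), and CAN1, an arginine permease gene (-0.35 ± 0.08). UGA3 did not pass without the 0 min a (-0.39), 0 min b (-0.39), 30 min a (-0.40) or 30 min b array (-0.38), nor with culture pair as replicate block (adjusted p = 0.0640), and CAN1 not without the 0 min a (-0.36), 0 min b (-0.34) or 30 min a array (-0.26). Neither passed with median centring (adjusted p = 0.0582 and 0.141), without the dye term (adjusted p = 0.0672 and 0.211), with only the rap1-303-aa arrays (adjusted p = 0.112 and 0.169) or with array weights (adjusted p = 0.172 and 0.232). Amino acid biosynthesis had 2 falls among 35, over all genes and adjusted over the list alone (mean -0.08, adjusted p = 0.151). They were those of HIS4 of histidine synthesis (-1.08 ± 0.10) and SER1 of serine synthesis (-0.43 ± 0.09), which did not pass without the 0 min a (-0.47), 0 min b (-0.40) or 30 min a array (-0.36), nor with median centring (adjusted p = 0.316), no dye term (adjusted p = 0.0773), the spot median (adjusted p = 0.221), array weights (adjusted p = 0.102) or only the rap1-303-aa arrays (adjusted p = 0.0696). The number of changed genes was 130 without the 0 min a array and 159 without the 0 min b array, 574 with print-tip loess, 620 from the deposited ratios (353 falls and 267 rises) and 23 after normalization on external controls.

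In reb1-aa, 619 of 5315 genes fell and 196 rose by 30 min, 175 and 10 of them beyond 1 log2 unit. PRE9, a core proteasome subunit gene, fell by 3.33 ± 0.08 on the log2 scale (limma adjusted p = 1.06e-07, n = 2 cultures per time). MDM35 of the mitochondrial intermembrane space (-2.84 ± 0.10), the splicing factor gene SNT309 (-2.67 ± 0.08), TOM5 of the mitochondrial import channel (-2.65 ± 0.17), OST4 of protein N-glycosylation (-2.62 ± 0.09), YKL033W-A (-2.56 ± 0.12) and APL4, a clathrin adaptor subunit gene (-2.51 ± 0.08), also fell. They were followed by EMC6 of the ER membrane complex (-2.37 ± 0.17), GPI12 of lipid anchor synthesis (-2.32 ± 0.07) and the coactivator gene MBF1 (-2.30 ± 0.22). The largest rise was that of MAM1, a meiotic monopolin gene (2.08 ± 0.08, adjusted p = 2.71e-07), and COM2, a zinc finger protein gene, rose by 1.27 ± 0.08 and CIT2 by 1.02 ± 0.09.

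Nitrogen catabolite genes rose in reb1-aa, 9 of 27 with no fall (10 adjusted over the list alone), with a mean of 0.33 (camera adjusted p = 8.69e-08; adjusted p = 0.0737 with an estimated correlation). DAL80, a GATA-type repressor gene, rose by 1.32 ± 0.10, the ammonium permease gene MEP2 by 1.21 ± 0.21 and the general amino acid permease gene GAP1 by 1.05 ± 0.12. General stress genes rose too, 22 of 36 with no fall (28 adjusted over the list alone), with a mean of 0.54 (camera adjusted p = 2.54e-15; adjusted p = 0.266 with an estimated correlation). TSL1 of trehalose synthesis rose by 1.25 ± 0.16, PGM2 by 1.20 ± 0.19, HXK1 by 1.06 ± 0.17 and the small heat shock protein gene HSP12 by 1.07 ± 0.27. HSP12 did not pass without the 0 min b array (0.89, adjusted p = 0.188) or the 30 min a array (0.74, adjusted p = 0.238).

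Ribosome biogenesis genes fell in reb1-aa, 31 of 79 with no rise (46 adjusted over the list alone), with a mean of -0.40 (camera adjusted p = 4.97e-15; adjusted p = 0.266 with an estimated correlation). PUF6, which encodes a nucleolar RNA-binding protein, fell by 1.21 ± 0.14 and the helicase gene HAS1 by 1.12 ± 0.14. Of RNA polymerase I and III subunits, 2 of 19 fell, over all genes and adjusted over the list alone, with a mean of -0.24 (camera adjusted p = 0.00212; adjusted p = 0.249 with an estimated correlation). RPA190, the largest polymerase I subunit, was at -0.59 ± 0.10. RPA49 of the same enzyme (-0.38 ± 0.10) did not pass without the 0 min a (-0.30), 0 min b (-0.45), 30 min a (-0.43) or 30 min b array (-0.32), with plain background subtraction (adjusted p = 0.0551), print-tip loess (-0.23, adjusted p = 0.0561) or no dye term (adjusted p = 0.106). That list did not pass after normalization on external controls (mean -0.09, adjusted p = 0.151). Oxidative phosphorylation genes had 1 rise and 4 falls among 36, over all genes and adjusted over the list alone. ATP4 (-1.03 ± 0.11) and ATP5 (-0.61 ± 0.07), both of the ATP synthase, fell, but the list had a mean of 0.06 and a call upwards in camera (adjusted p = 0.0362; adjusted p = 0.658 with an estimated correlation). It was lost without the 0 min a array (mean 0.04, adjusted p = 0.0957) or the 30 min b array (mean 0.03, adjusted p = 0.123), with median centring (adjusted p = 0.134), normalization on external controls (mean 0.20, adjusted p = 0.224), the spot median (adjusted p = 0.0692) and by fry (adjusted p = 0.519).

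Single members fell strongly in lists that did not pass camera in reb1-aa. By fry, proteasome subunits (adjusted p = 0.00108), mitochondrial ribosomal proteins (adjusted p = 0.0141) and translation factors (adjusted p = 0.0465) passed. Proteasome genes had 9 falls among 32 (10 adjusted over the list alone; median 0.00, mean -0.34, adjusted p = 0.112). PRE6 stood at -2.25 ± 0.06 besides PRE9. Mitochondrial ribosomal protein genes had 17 falls and 1 rise among 70, over all genes and adjusted over the list alone (mean -0.19, adjusted p = 0.201). MRPL23 stood at -1.87 ± 0.12 and RSM10 at -1.83 ± 0.10. Heat shock factor chaperones had 5 rises and 5 falls among 17, over all genes and adjusted over the list alone (median 0.16, mean -0.11, test up, adjusted p = 0.601). The largest falls were of SIS1, an Hsp40 gene (-1.89 ± 0.14), and AHA1, an activator of Hsp90 (-1.85 ± 0.17). Translation factors had 5 falls among 25 (7 adjusted over the list alone; mean -0.19, adjusted p = 0.0762), with PRT1, an initiation factor subunit gene, at -0.82 ± 0.21 and the cap-binding protein gene CDC33 at -0.74 ± 0.09. PRT1 did not pass without the 0 min b (-0.61), 30 min a (-0.69) or 30 min b array (-0.94), with median centring (adjusted p = 0.0610) or without the dye term (adjusted p = 0.0904). Amino acid biosynthesis had 3 falls among 35 (2 adjusted over the list alone; median 0.01, mean -0.02, test up, adjusted p = 0.486), with HIS5 of histidine synthesis at -1.45 ± 0.12. ARG3 of arginine synthesis (-0.35 ± 0.08) did not pass without the 0 min a (-0.36), 0 min b (-0.34), 30 min a (-0.37) or 30 min b array (-0.32), with median centring (adjusted p = 0.0842) or the spot median (adjusted p = 0.0728). Haploid-specific genes had 1 rise and 1 fall among 16, over all genes and adjusted over the list alone (mean -0.10, adjusted p = 0.896). RME1, a repressor gene of meiosis, rose by 0.62 ± 0.11 (adjusted p = 0.0881 without the dye term) and STE18, the pheromone G protein gamma subunit gene, fell by 1.65 ± 0.09.

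The other reb1-aa means were -0.05 for cytosolic ribosomal proteins (adjusted p = 0.896), -0.03 for the 6 Abf1-associated genes (median -0.06, test up, adjusted p = 0.976), 0.08 for glycolysis and fermentation (adjusted p = 0.179), -0.02 for a-specific (test up, adjusted p = 0.976) and 0.07 for alpha-specific genes (adjusted p = 0.590), 0.01 for subtelomeric families (adjusted p = 0.403) and 0.14 for core histones (adjusted p = 0.140). No member of these 7 lists passed limma's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1 cytosolic ribosomal protein gene and 1 glycolysis gene, with 0 in the 5 others. The number of changed genes was 535 without the 0 min b array and 503 without the 30 min a array, 84 after normalization on external controls (77 falls and 7 rises), and 2828 when the reb1-aa arrays were fitted alone. In that last fit falls and rises were closer in number (1552 and 1276, or 54.9% falls, against 76.0% of the 815), as with array weights (1470 and 1168).

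**Figure D1:**
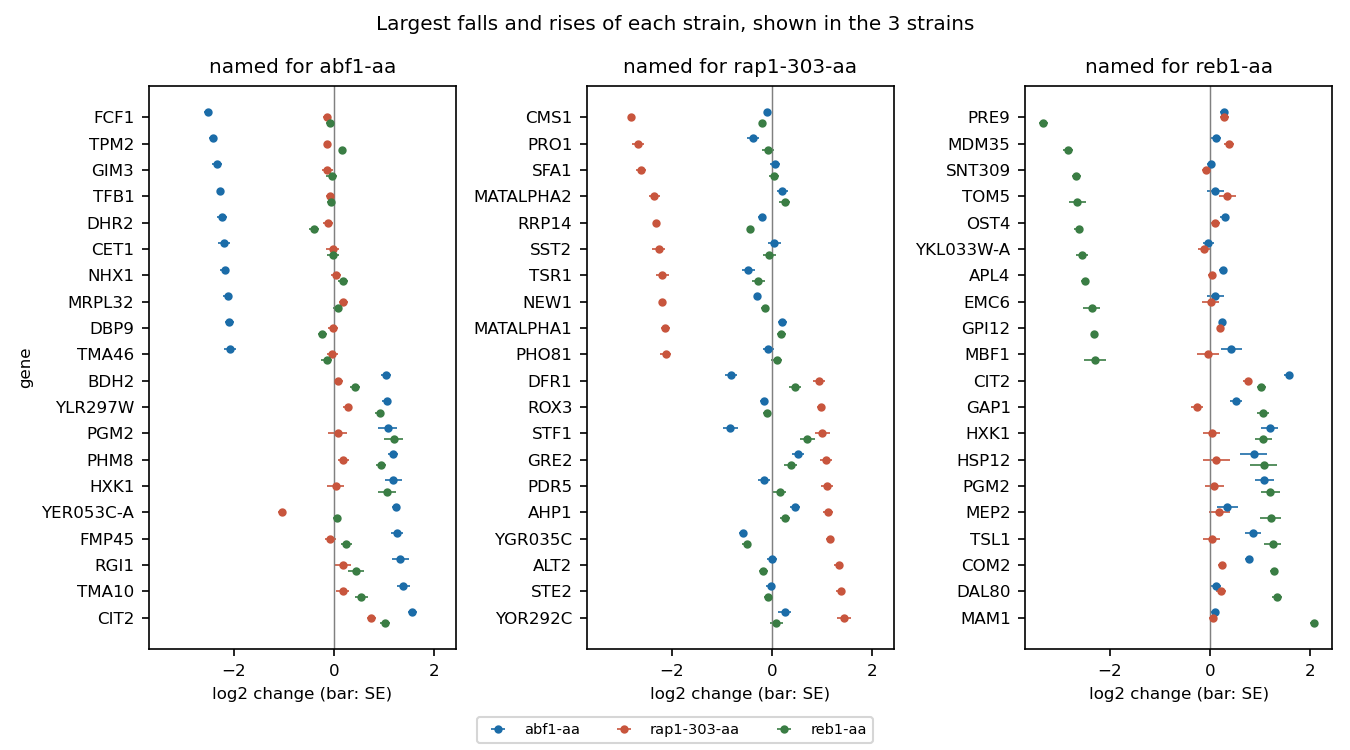
Log2 change from 0 to 30 min (x axis, points, with the standard error of limma as bars, 2 cultures per time) for the 10 largest falls and 10 largest rises of each strain (y axis, 1 panel per strain), shown in all 3 strains. FCF1 stood at -2.52 in abf1-aa against -0.14 and -0.08 in the 2 other strains, and CIT2 was above 0 in all 3.

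Changes common to the 3 strains were compared because no strain without a tagged factor is among the samples. Across all genes, which are not independent replicates, changes correlated with r of 0.09 between abf1-aa and rap1-303-aa, 0.07 between abf1-aa and reb1-aa and 0.03 between rap1-303-aa and reb1-aa. Spearman correlations were higher, at 0.27, 0.28 and 0.15. Each gene has the same SE in the 3 strains, so the lists of changed genes are not fully independent and the p values here are approximate. Falls coincided no more than expected: 84 genes fell in both abf1-aa and reb1-aa (86.8 expected for independent lists, Fisher's exact adjusted p = 0.805) and 21 in both abf1-aa and rap1-303-aa (30.6 expected, adjusted p = 0.117). Fewer than expected, 9, fell in both rap1-303-aa and reb1-aa (25.4 expected, adjusted p = 0.000322). Rises coincided more: 110 genes rose in both abf1-aa and reb1-aa (12.7 expected, adjusted p = 6.63e-83), 33 in both abf1-aa and rap1-303-aa (5.78 expected, adjusted p = 8.46e-17) and 22 in both rap1-303-aa and reb1-aa (3.28 expected, adjusted p = 1.70e-12).

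In all 3 strains, 14 genes rose and 5 fell, against 0.213 and 3.56 expected for independent lists. The numbers were 19 and 19 with print-tip loess and 4 and 7 with array weights. CIT2 rose by 1.56 in abf1-aa, 0.75 in rap1-303-aa and 1.02 in reb1-aa (SE 0.09 each), and CIT1, the mitochondrial citrate synthase gene, by 0.84, 0.55 and 0.92 (SE 0.08). PDH1 of propionate metabolism (0.81, 0.80 and 0.59), the pyruvate carboxylase gene PYC1 (0.69, 0.50 and 0.67) and the plasma membrane protein gene YRO2 (0.89, 0.68 and 0.71) rose as well. The 5 that fell were MMP1, an S-methylmethionine permease gene (-0.58, -0.63 and -0.48), GFD2 (-0.61, -0.66 and -0.42), YNL162W-A (-0.46, -0.83 and -0.34), MET17 of methionine synthesis (-0.33, -0.88 and -0.35) and the nucleolin gene NSR1 (-0.34, -0.52 and -0.33). Without the rap1-303-aa 0 min a array 3 shared genes were left, and YRO2 (0.56, adjusted p = 0.123), PDH1 (0.80, adjusted p = 0.0783), CIT1 (0.50, adjusted p = 0.0623) and PYC1 (0.41, adjusted p = 0.165) no longer passed in that strain. PDH1 in that strain also did not pass without the 0 min b array (0.81, adjusted p = 0.0648), and in reb1-aa without its 0 min a (0.45, adjusted p = 0.146) or 30 min b array (0.51, adjusted p = 0.125). Nor did PYC1 pass in rap1-303-aa without the 30 min a array (0.50, adjusted p = 0.0530). The 5 that fell lost their call in reb1-aa without its 30 min a array: MMP1 (-0.45, adjusted p = 0.0731), GFD2 (-0.42, adjusted p = 0.214), YNL162W-A (-0.29, adjusted p = 0.323), MET17 (-0.33, adjusted p = 0.0938) and NSR1 (-0.39, adjusted p = 0.121). With culture pair as replicate block GFD2 did not pass in reb1-aa either (adjusted p = 0.0864). More calls of these 5 ended without other arrays, at adjusted p between 0.0523 and 0.410. In reb1-aa this held without the 0 min a array for GFD2 (-0.37), YNL162W-A (-0.44), MET17 (-0.37) and NSR1 (-0.30), without the 0 min b array for MMP1 (-0.40), GFD2 (-0.47), YNL162W-A (-0.23), MET17 (-0.32) and NSR1 (-0.36), and without the 30 min b array for GFD2 (-0.41), YNL162W-A (-0.39), MET17 (-0.36) and NSR1 (-0.27). In rap1-303-aa it held without the 0 min a array for MMP1 (-0.62), GFD2 (-0.49) and NSR1 (-0.43), and without the 30 min a array for GFD2 (-0.59). In abf1-aa it held without the 0 min a array for YNL162W-A (-0.44), MET17 (-0.30) and NSR1 (-0.39), without the 0 min b array for YNL162W-A (-0.48) and NSR1 (-0.30), and without the 30 min a array for YNL162W-A (-0.39), MET17 (-0.26) and NSR1 (-0.20). Median centring ended calls of MMP1, GFD2, YNL162W-A, MET17 and NSR1 in reb1-aa (adjusted p between 0.0518 and 0.210), of GFD2 in rap1-303-aa (adjusted p = 0.0678) and of MET17 and NSR1 in abf1-aa (adjusted p = 0.252 and 0.221). Array weights ended those of YRO2, PDH1, CIT1, PYC1, GFD2 and NSR1 in rap1-303-aa (adjusted p between 0.0580 and 0.115). Without the rap1-303-aa 0 min b array 11 shared genes were left, without 1 of the reb1-aa arrays 8 or 9, and after normalization on external controls 0, where MET17 and NSR1 stood at 0.12 and 0.09 in abf1-aa.

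Differences between strains were tested as interactions of strain and time. Between rap1-303-aa and abf1-aa 784 genes differed, 523 higher and 261 lower in the change of rap1-303-aa. The phosphatidylserine synthase gene CHO1 differed by 2.66 ± 0.12 (0.61 in rap1-303-aa and -2.05 in abf1-aa), FCF1 by 2.38 ± 0.11 and MRPL32 by 2.31 ± 0.13. CMS1 (-2.72 ± 0.09), SFA1 (-2.68 ± 0.14) and MATALPHA2 (-2.56 ± 0.15) differed the other way. Between reb1-aa and abf1-aa 1047 genes differed, 507 higher and 540 lower in reb1-aa. PRE9 was at -3.61 ± 0.12, MDM35 at -2.96 ± 0.14, OST4 at -2.91 ± 0.13, TPM2 at 2.58 ± 0.09, FCF1 at 2.44 ± 0.11 and NHX1 at 2.37 ± 0.14. Between rap1-303-aa and reb1-aa 741 genes differed, 520 higher and 221 lower in rap1-303-aa. PRE9 was at 3.62 ± 0.12, MDM35 at 3.21 ± 0.14 and TOM5 at 2.99 ± 0.24, against SFA1 at -2.65 ± 0.14, CMS1 at -2.62 ± 0.09 and MATALPHA2 at -2.61 ± 0.15. The background of rap1-303-aa, and MET17 at 0 min between abf1-aa and reb1-aa, differ between strains, so these contrasts hold only as far as such differences act alike at 0 and 30 min. After normalization on external controls the balance turned downwards between rap1-303-aa and abf1-aa (12 higher and 18 lower) and moved downwards between reb1-aa and abf1-aa (13 and 69), with 37 higher and 14 lower between rap1-303-aa and reb1-aa.

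Whole lists differed between strains in camera. The mean change of cytosolic ribosomal protein genes in rap1-303-aa lay 0.31 below that of abf1-aa (adjusted p = 5.49e-10; adjusted p = 0.306 with an estimated correlation) and 0.32 below that of reb1-aa (adjusted p = 2.25e-12; adjusted p = 0.306 with an estimated correlation). General stress genes changed less in that strain, with differences of -0.68 against abf1-aa (adjusted p = 3.55e-13; adjusted p = 0.322 with an estimated correlation) and -0.54 against reb1-aa (adjusted p = 1.82e-09; adjusted p = 0.439 with an estimated correlation and 0.0532 by fry). In these contrasts 15 and 9 of the 36 genes were lower by the interaction test. The change of ribosome biogenesis genes was higher in reb1-aa than in abf1-aa by 0.28 (adjusted p = 0.000630; adjusted p = 0.743 with an estimated correlation and 0.0618 by fry).

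**Figure D2:**
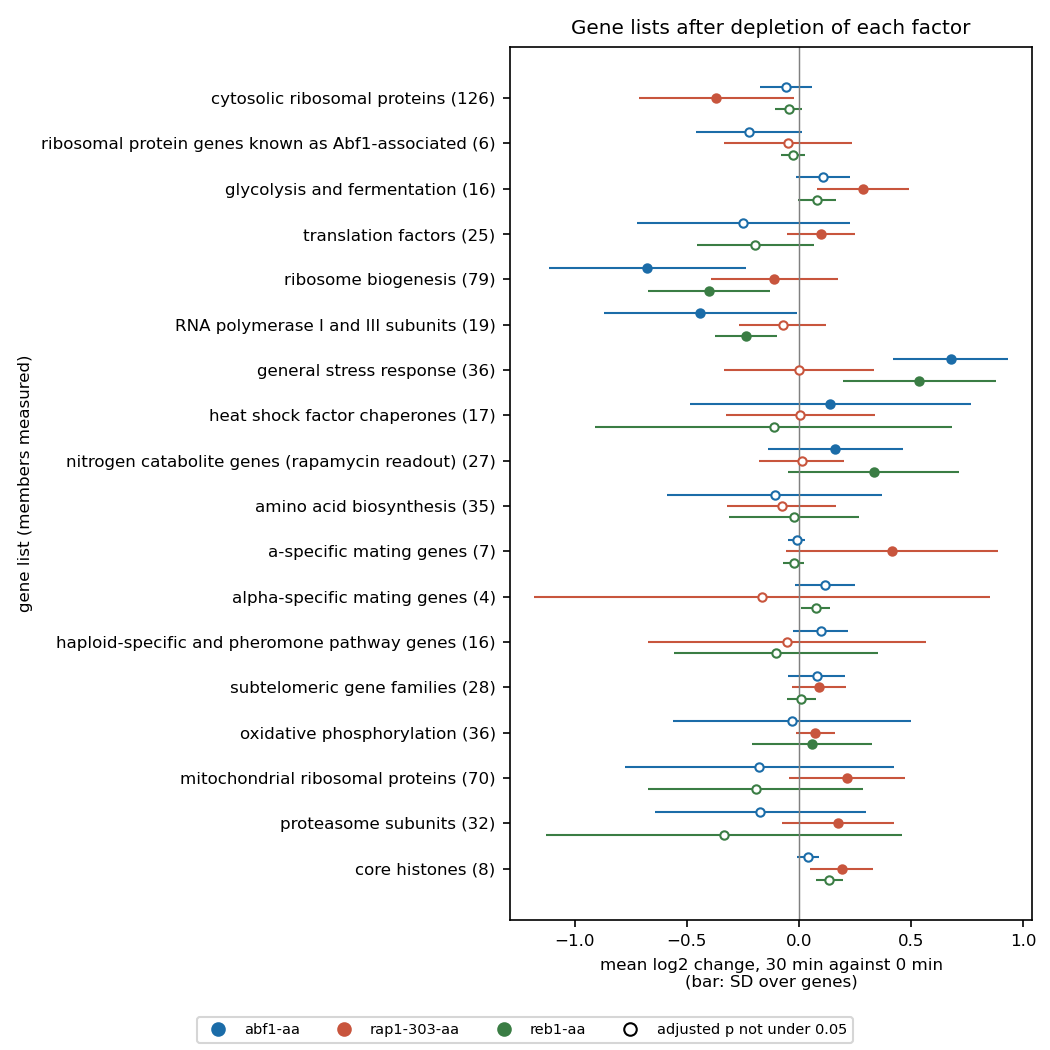
Mean log2 change from 0 to 30 min (x axis) of the 18 gene lists (y axis, number of measured members in brackets) in the 3 strains, with bars for the standard deviation over genes. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, such as ribosome biogenesis in abf1-aa (-0.68, relative to the median gene), and the small negative mean of that list in rap1-303-aa (-0.11) was 0.05 after normalization on external controls.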

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

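The tests of lower MATALPHA transcripts, of HML, of cells of mating type a and of a response common to the strains were chosen after the results were seen. Changes from 0 to 30 min differed between strains. The interaction of strain and time passed limma's test at an adjusted p under 0.05 for 784 genes between rap1-303-aa and abf1-aa, 1047 between reb1-aa and abf1-aa and 741 between rap1-303-aa and reb1-aa. The genes with the largest differences were CMS1 (-2.72), SFA1 (-2.68), MATALPHA2 (-2.56), CHO1 (2.66), FCF1 (2.38) and MRPL32 (2.31) for rap1-303-aa against abf1-aa. For reb1-aa against abf1-aa they were PRE9 (-3.61), MDM35 (-2.96), OST4 (-2.91), TPM2 (2.58), FCF1 (2.44) and NHX1 (2.37). For rap1-303-aa against reb1-aa they were SFA1 (-2.65), CMS1 (-2.62), MATALPHA2 (-2.61), PRE9 (3.62), MDM35 (3.21) and TOM5 (2.99).

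Between rap1-303-aa and abf1-aa, 8 lists differed in camera. They were cytosolic ribosomal proteins (-0.31), translation factors (0.35, but -0.03 after normalization on external controls), ribosome biogenesis (0.57), RNA polymerase I and III subunits (0.37), general stress response (-0.68), a-specific mating genes (0.43), mitochondrial ribosomal proteins (0.39) and proteasome subunits (0.35). With an estimated correlation 0 lists passed, and 3 did at an unadjusted p under 0.05, namely cytosolic and mitochondrial ribosomal proteins and nitrogen catabolite genes, the last of which is not among the 8. By fry these 8 and the nitrogen catabolite genes passed. Between rap1-303-aa and reb1-aa, 8 differed in camera, 0 with an estimated correlation (4 of them at an unadjusted p under 0.05), and 6 of them by fry, without ribosome biogenesis and general stress response. The 8 were cytosolic ribosomal proteins (-0.32), translation factors (0.29), ribosome biogenesis (0.29), general stress response (-0.54), nitrogen catabolite genes (-0.32), a-specific mating genes (0.44), mitochondrial ribosomal proteins (0.41) and proteasome subunits (0.51). Between reb1-aa and abf1-aa, ribosome biogenesis differed in camera (0.28), but not by fry (adjusted p = 0.0618), and 0 lists passed with an estimated correlation, also at an unadjusted p under 0.05. The 3 lists that passed by fry there were others. Without the rap1-303-aa 30 min b array the a-specific genes no longer passed against abf1-aa (0.38, adjusted p = 0.0584) or reb1-aa (0.40, adjusted p = 0.0584). Without the 30 min a array translation factors no longer passed against reb1-aa (0.21, adjusted p = 0.0584). With median centring the a-specific genes against reb1-aa (0.41, adjusted p = 0.163) and translation factors against abf1-aa (0.26, adjusted p = 0.0792) did not pass either, nor did these with normalization on external controls (0.34 and -0.03, adjusted p = 0.138 and 0.147).

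Among the 1062 gene probes with no single name, which the comparisons did not use, 91 passed limma's test in abf1-aa (50 up, 41 down), 66 in rap1-303-aa (12 up, 54 down) and 62 in reb1-aa (29 up, 33 down) when all gene probes were tested together.

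General stress genes rose in abf1-aa and reb1-aa (means 0.68 and 0.54) but had a mean of 0.00 in rap1-303-aa. In camera the test of the difference against each other strain had a larger adjusted p of 1.82e-09. It restates on the same arrays the difference that raised the question. It therefore gives no separate support for or against a response to rapamycin or handling common to all strains. Both differences were lost, however, with an estimated correlation (adjusted p = 0.322 and 0.439), and that against reb1-aa also by fry (adjusted p = 0.0532). Ratios compressed by background on the dimmer rap1-303-aa arrays should give a mean of at least 0.29 with plain background subtraction, by a prediction written before that test. The mean was 0.0250, so the prediction was not met. Plain subtraction moved the mean in rap1-303-aa little, from 0.00, and it was 0.74 in abf1-aa and 0.59 in reb1-aa. The SD over the 36 genes (0.39) is the spread among genes and does not measure the error of this mean. That error was not estimated, so a smaller part for this cause was not tested. The strain background and the depleted factor of rap1-303-aa differ together from those of the 2 other strains, so they remain open and cannot be told apart.

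In rap1-303-aa, MATALPHA1, MATALPHA2 and STE3 fell and 3 a-specific genes rose. The labels do not give the mating type of this strain. At 0 min its log2 ratios to the MATalpha reference were -0.02 ± 0.03 for MATALPHA1 and -0.08 ± 0.15 for STE2 (SD, n = 2). Both MATALPHA probes were well above background on 4 of 4 arrays. These levels are those of an alpha strain and argue against a strain of mating type a with a silent HML. The probes match both copies, so signal from MAT and from HML was not separated. The higher upper 95% bound of the MATALPHA1 and MATALPHA2 changes was -1.93, so the summed signal of MAT and HML fell. This restates the fall that raised the question and is no separate test of HML. Derepression of HML hidden under a larger fall stays open. Replacement of alpha cells by cells of mating type a in the 30 min cultures, which presumes an alpha strain, was argued against as the whole cause. The median change of the 4 measured alpha-specific genes was 0.15 (SD 1.02), above -1.06, which is 50% of the MATALPHA1 change, by more than the SD. MF(ALPHA)1, MF(ALPHA)2 and SAG1 lay above that bound, but STE3 (-1.64 ± 0.12) went the other way and lay below it. Lower MATALPHA transcripts may lie behind the changes of the mating genes, but this stays undecided (7 a-specific genes, mean 0.42, SD 0.47, against 4 alpha-specific genes, mean -0.17, SD 1.02; one-sided exact permutation p = 0.158 over 330 splits). HMR stays open as well, because HMRA1 (-0.03, bounds -0.22 to 0.17) lay near the background.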

How the results depend on the processing

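The spot median, array weights, all probes and crossed pairing were alternatives chosen after the data were seen. The number of changed genes stayed within 1.5 times without background subtraction, with plain subtraction, with trend and robust settings, without the dimmest 25% of probes and with the spot median, in the 3 strains. Aquantile scaling leaves log ratios as they are by construction. With culture pair as replicate block, 1002, 251 and 772 genes changed in abf1-aa, rap1-303-aa and reb1-aa, 743, 999 and 697 differed between strains and 16 were shared. GFD2 then lost its call in reb1-aa (adjusted p = 0.0864). With crossed pairing, 1230 changed in abf1-aa and 300 in rap1-303-aa, and with all 6388 probes tested 1178, 373 and 890 passed.

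In abf1-aa, 1090 genes changed, against 718 with median centring, 51 with normalization on external controls and 687 with only its own arrays. In rap1-303-aa, 307 changed, against 574 with print-tip loess, 23 with external controls, 185 without the dye term, 620 from the deposited ratios and 124 with array weights. In reb1-aa, 815 changed, against 84 with external controls, 2828 with only its own arrays, 1270 from the deposited ratios and 2638 with array weights. Between strains, 30, 82 and 51 genes differed with external controls (rap1-303-aa against abf1-aa, reb1-aa against abf1-aa, rap1-303-aa against reb1-aa), and 1190 in the last from the deposited ratios. The cause was not tested for these, but the spread differed between strains. The a and b changes of reb1-aa differed by an SD of 0.07 across genes, against 0.28 in abf1-aa and 0.27 in rap1-303-aa. Array weights were 5.22, 0.521 and 0.367 in the same order. Under the pooled spread, counts of changed genes are therefore not comparable between strains. In a fit of 1 strain the dye term also takes up the difference between its letters. External controls moved the median of all genes by 0.37 in abf1-aa, 0.11 in rap1-303-aa and 0.16 in reb1-aa, so all changes are relative to the median gene. A call lost with external controls need not mean a smaller change. ABF1 in abf1-aa was at 0.78 with them, against 0.42 in the main fit, and did not pass.

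Stricter thresholds lower counts by construction: at an adjusted p under 0.01, 679 genes passed in abf1-aa, 165 in rap1-303-aa and 517 between these 2, and with a 1.7-fold minimum 353, 90 and 285 in the 3 strains and 418, 592 and 387 between them. Leaving out 1 array left groups of 1, whose spread is assumed to be that of the others. Counts then ranged from 620 to 962 in abf1-aa, 130 to 420 in rap1-303-aa and 503 to 556 in reb1-aa, and between strains from 546 to 1034, 825 to 960 and 522 to 940. The lowest came without the abf1-aa 0 min b (620), rap1-303-aa 0 min a (130) and reb1-aa 30 min a array (503), and other counts beyond 1.5 times were 723 without abf1-aa 30 min b, 159 without rap1-303-aa 0 min b and 535 without reb1-aa 0 min b.

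Of 19 genes shared by the 3 strains in 1 direction, counts were 8 with median centring, 38 with print-tip loess, 0 with external controls, 8 without the dye term, 52 from the deposited ratios, 7 at an adjusted p under 0.01, 0 with the fold minimum, 11 with array weights and 3 to 26 without 1 array. The cause was not tested, except for the thresholds.

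Camera called 5 lists in abf1-aa, 10 in rap1-303-aa and 5 in reb1-aa. With an estimated correlation the counts were 0, 0 and 0 (4, 5 and 1 at an unadjusted p under 0.05), and by fry 10, 6 and 7, which are not all lists that camera called. In rap1-303-aa, 6 passed with median centring, 6 with print-tip loess, 5 with external controls, 6 with its own arrays and 6 from the deposited ratios. Without 1 array the numbers were 4 to 8, 7 to 8 and 5 to 6. The cause was not tested.

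Of 163 calls of named genes, those kept in direction and side of the threshold numbered 162 without background subtraction, 161 with print-tip loess, 161 from the deposited ratios, 145 without the dye term, 144 with median centring and 83 with external controls, where 3 genes changed sign in abf1-aa: RPP1 (0.00115), MET17 (0.12) and NSR1 (0.0875). For ribosome biogenesis in rap1-303-aa the mean ranged from -0.21 to -0.0078 without 1 array, and the test changed direction without the 30 min b array. The alternative on spot flags was not run, as no flags are given, nor were the lists by motif and telomere distance. No gene picked by the rule for named genes was dim, but HMRA1, named for the mating genes, lay near the background.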

Other observations

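The test of print distance was chosen after the result was seen, and the genes and pairs named here were chosen after their values were seen. Some genes moved in opposite directions in different strains, but no more than expected for independent lists. From abf1-aa to rap1-303-aa, 12 genes rose in the first and fell in the second (14.2 expected), and 9 the other way (12.5 expected). Between abf1-aa and reb1-aa the numbers were 34 (40.2 expected) and 10 (27.5 expected, Fisher's exact adjusted p = 0.000256). Between rap1-303-aa and reb1-aa they were 12 (10.4 expected) and 9 (8.04 expected). CHO1 fell by 2.05 ± 0.09 on the log2 scale in abf1-aa and rose by 0.61 ± 0.09 in rap1-303-aa (SE of limma, n = 2 cultures per time). YER053C-A rose by 1.23 ± 0.08 in abf1-aa and fell by 1.04 ± 0.08 in rap1-303-aa, and RTS2, linked to DNA replication, rose by 0.57 ± 0.08 in abf1-aa and fell by 2.03 ± 0.08 in reb1-aa. MRPL51 of the mitochondrial ribosome fell by 1.10 ± 0.06 in abf1-aa and rose by 0.49 ± 0.06 in reb1-aa, and ECM29, a proteasome-associated gene, rose by 0.47 ± 0.07 in rap1-303-aa and fell by 1.59 ± 0.07 in reb1-aa.

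Whether culture letters pair the 0 and 30 min cultures was not settled by the values in any strain. In reb1-aa each letter carries its own isolate number at both times. Across genes, deviations of the letters at 0 and 30 min correlated with r of -0.65 in abf1-aa, -0.20 in rap1-303-aa and 0.81 in reb1-aa after the dye effect was removed. Before that they were 0.24, 0.65 and 0.77, against 0.26 to 0.47 between different strains. The values after removal cannot decide on pairing, because the dye effect was the mean of the same letter differences, which ties the deviations together. Before the removal rap1-303-aa and reb1-aa lay above the range between strains, as pairing would give. A shared dye effect with little noise would give this too.

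Neighbouring genes fell together more often than shuffled genes, with 159 pairs of 4443 in abf1-aa (87.2 expected), 27 in rap1-303-aa (7.45 expected) and 113 in reb1-aa (60.2 expected). The permutation p was 1e-05 in each strain, the smallest that 100000 shuffles can give. Divergent pairs, whose upstream regions face each other, stood out. In abf1-aa both members fell in 71 of 267 divergent pairs with a fallen member (26.6%) against 88 of 857 other pairs (10.3%). The numbers were 16 of 80 against 11 of 255 in rap1-303-aa and 63 of 234 against 50 of 708 in reb1-aa (Fisher's exact p = 3.3e-10, 4.10e-05 and 4.37e-14 in abf1-aa, rap1-303-aa and reb1-aa). Fisher's test takes pairs as independent, although 1 gene can belong to 2 pairs, so these p values and the bounds below are approximate. The shuffles tested the number of pairs, not the contrast of divergent with other pairs. Examples were CDC10 and MRPL32 in abf1-aa (-1.89 and -2.12), MATALPHA2 and MATALPHA1 in rap1-303-aa (-2.35 and -2.13) and SPN1 and TOM5 in reb1-aa (-1.21 and -2.65). Probes printed close together were argued against, since the nearest spots of divergent pairs lay at 103% of the distance in other pairs. A tendency of divergent neighbours to move together in any response was argued against in abf1-aa, where the odds ratio of both members rising was 0.825 (upper bound 2.12, under the lower bound of 2.19 for falls), and stays undecided in rap1-303-aa (2.97) and reb1-aa (1.08). A shared upstream region may link these falls, which remains a hypothesis, since no binding site or nucleosome was examined.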
